A study of Mus musculus with 18 samples.

How the data were processed

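Genomic DNA from tail tissue of 9 mice of 1 family (a sire, a dam and 7 offspring, C57BL/6 per the labels) was compared with the DNA of 1 reference male by 2-colour array comparative genomic hybridisation, in which 2 DNAs carrying different dyes compete for the same probes and their ratio reports relative copy number. Each animal was hybridised on 2 arrays with the dyes exchanged, which gave 18 arrays on 5 slides. The series belongs to a study of males kept under 1 mGy per day of gamma rays for 400 days, per the labels. The title of the series places this family among the exposed, whereas its design text calls the sire non-irradiated, so the sire's exposure was left open and no exposure comparison was made. All comparisons were within the family.

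Per the file headers, the deposited scanner files came from Agilent Feature Extraction 10.7.1.1 with a CGH protocol, a linear dye normalisation without lowess, and probe coordinates on mouse build mm9 (NCBI37). The deposited intensity values used were the processed signals of both channels, background-subtracted and dye-normalised per the file headers. The deposited log10 ratio column (red over green) and the spot flags were also read. The series also deposited a table of log2 values. Set against the scanner values of the same arrays, that table held log2 of reference over animal on every array (lowest absolute r of 0.968), with column medians between -0.0026 and 0.0097, and its processing is not given in the sources used here. All log2 ratios given here are animal over reference, which is the opposite direction to that table.

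The array held 140213 genomic spots for 136106 distinct probes, of which 136055 lay on autosomes, 48 on X and 3 on Y. Splitting the autosomal probes at gaps above 5000 bp, a rule set after the array layout was seen, gave 3851 densely tiled stretches of 5 or more probes (median 36 probes) and 3733 isolated probes. Control spots and spots flagged as outliers (at most 189 per array) were left out. The median processed signal of an array lay between 1050 and 1122 in either channel, no spot was saturated, and at most 238 genomic spots per array were not well above background. The number of arrays limits the precision.

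For each array the log2 ratio was centred on the median over genomic probes, turned to animal over reference, averaged over the spots of a probe and then over both dye orientations. Autosomal ratios were segmented by least-squares change points (penalty of 25 noise variances per change point). A segment was called with at least 5 probes, a mean of at least 0.3 in size, and the same sign with at least 0.2 in each dye orientation. Overlapping segments of the same direction in different animals were merged into a region. An animal was a carrier by the same thresholds over the region, a non-carrier below 0.15 in size, and otherwise undecided. An offspring-only region had a carrier among the offspring and both parents as non-carriers. A segregating region had at least 1 carrier parent without being carried by all 9 animals. Each called mean was placed among 10000 random windows of as many consecutive probes outside called regions of the same animal. The calling rule was also run on the dye component (the part of the signal that turns with the dyes) as a count of false calls from the dyes only. Carriers among offspring were tested against even odds (0.5) with an exact two-sided binomial test and Benjamini-Hochberg adjustment. Offspring and parents were compared per probe with limma 3.58.1 (lmFit and eBayes) on 1 value per animal at an adjusted p of 0.05. The dye swap was treated as technical, so n counts animals. Segmentation ran in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0, and the exact tests in scipy 1.17.1.

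The calling rule was tested on simulated noise of each animal's size: of 180 planted segments with a shift of 0.5 and 5 probes, 178 were found, and no false call was made. That noise was independent between probes and dye orientations and sized by differences between neighbouring probes (0.16 in the sire and 0.14 in the dam). The real SD over probes was 0.31 in the sire and 0.24 in the dam. The simulation therefore gives no false-call rate for these arrays. The limma fit was tested on 135900 simulated probes with 200 changed. It recovered 56% of the changes of 0.3 and 92% of the changes of 0.6 in the comparison of offspring with parents. Its noise was independent between probes and animals. Parents and offspring alike were given the SD of each probe between the offspring. The real parents varied more over probes, and the simulation held no pattern shared by them. The recovery is therefore not the power of the real comparison.

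Text names every offspring-only region up to 15, the 10 largest segregating regions, the 10 largest regions shared by all 9 animals, and the 10 largest probes past the limma threshold with 1 per tiled stretch, by the rule fixed before the data were examined. Other loci are said to be chosen after their values were seen. The only annotation table in use here is of another mouse build, so regions are named by mm9 position. The 15 gene lists fixed beforehand, including lymphocyte receptor loci as a cell type marker, could not be matched to probes and were not run.

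Alternatives covered normexp background correction (offset 50) with loess, the deposited log ratio column, the deposited log2 table, centring on isolated probes, a filter on dim probes, other thresholds, segment sizes and penalties, each dye orientation alone, merging at 50% overlap, slide as a random block, tiled stretches as the unit, and leaving out each animal. In the normexp alternative the median spot signal took the place of the mean signal. A correction for base composition was planned and not run, since no probe sequences or mm9 genome were used here. After the data were seen, a minimum of 20 probes, means of whole tiled stretches, calling from the offspring alone, loess on the processed signals, scan day as a block or scan day 1 alone, and a limma fit of sire, dam and offspring as 3 groups were added.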

Results

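The copy number of autosomal segments was measured in tail DNA of a sire, a dam and their 7 offspring, each against the same reference male on 2 dye-swapped arrays. Each parent is 1 animal, and the 7 offspring are the only group with several animals. The array tiled 3851 short stretches of the genome at high density. The study asked whether chronic low-dose-rate gamma irradiation of males leaves copy number changes in their progeny, and this secondary array re-examined positions picked in a first screen of the family. The probes were therefore chosen for apparent changes and give no genome-wide rate.

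A gain on chromosome 4 was carried by the sire and by 2 of the 7 offspring. Across 544 probes from 101129151 to 101267436 (mm9), a span of 138286 bp, the mean log2 ratio of animal over reference was 0.54 in the sire, 0.51 in offspring 6 and 0.54 in offspring 7. This direction is the opposite of that in the deposited value table. The other 6 animals lay between -0.013 and -0.0036. The SD over probes was 0.31 in the sire, 0.10 in offspring 6 and 0.091 in offspring 7. Both dye orientations gave the gain, with 0.59 and 0.49 in the sire, 0.54 and 0.47 in offspring 6, and 0.57 and 0.50 in offspring 7. None of 10000 random windows of 544 probes reached these means, and the largest such window was 0.10 in the sire, 0.035 in offspring 6 and 0.043 in offspring 7. The windows left out every segment called in the same animal, so they could hardly reach such means. They show the size of the background and are no test of the gain. 3 copies against 2 correspond to a log2 ratio of 0.58. The nearest probe below the gain, at 101066373 to 101066432, read -0.034 in offspring 6 and -0.042 in offspring 7. The nearest probe above it, at 101613974 to 101614033, read -0.064 and 0.035. In these 2 offspring the gained segment was thus shorter than 547541 bp. The same flanking probes read -0.37 and 0.42 in the sire and -0.21 and 0.35 in the dam, which lacks the gain, and the uppermost called region ran to 101614107, so the sire's values set no upper limit. The calling rule divided the gain into 3 segregating regions with the same carriers. In each, 2 of 7 offspring carried the gain, with no departure from even odds detected (exact two-sided binomial p = 0.453, Benjamini-Hochberg adjusted p = 0.484). With 7 offspring the test can pass only if none or all carry. It therefore gives no evidence for even odds here. The gain lies outside the 10 regions taken by size and was singled out after its values were seen.

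**Figure D1:**
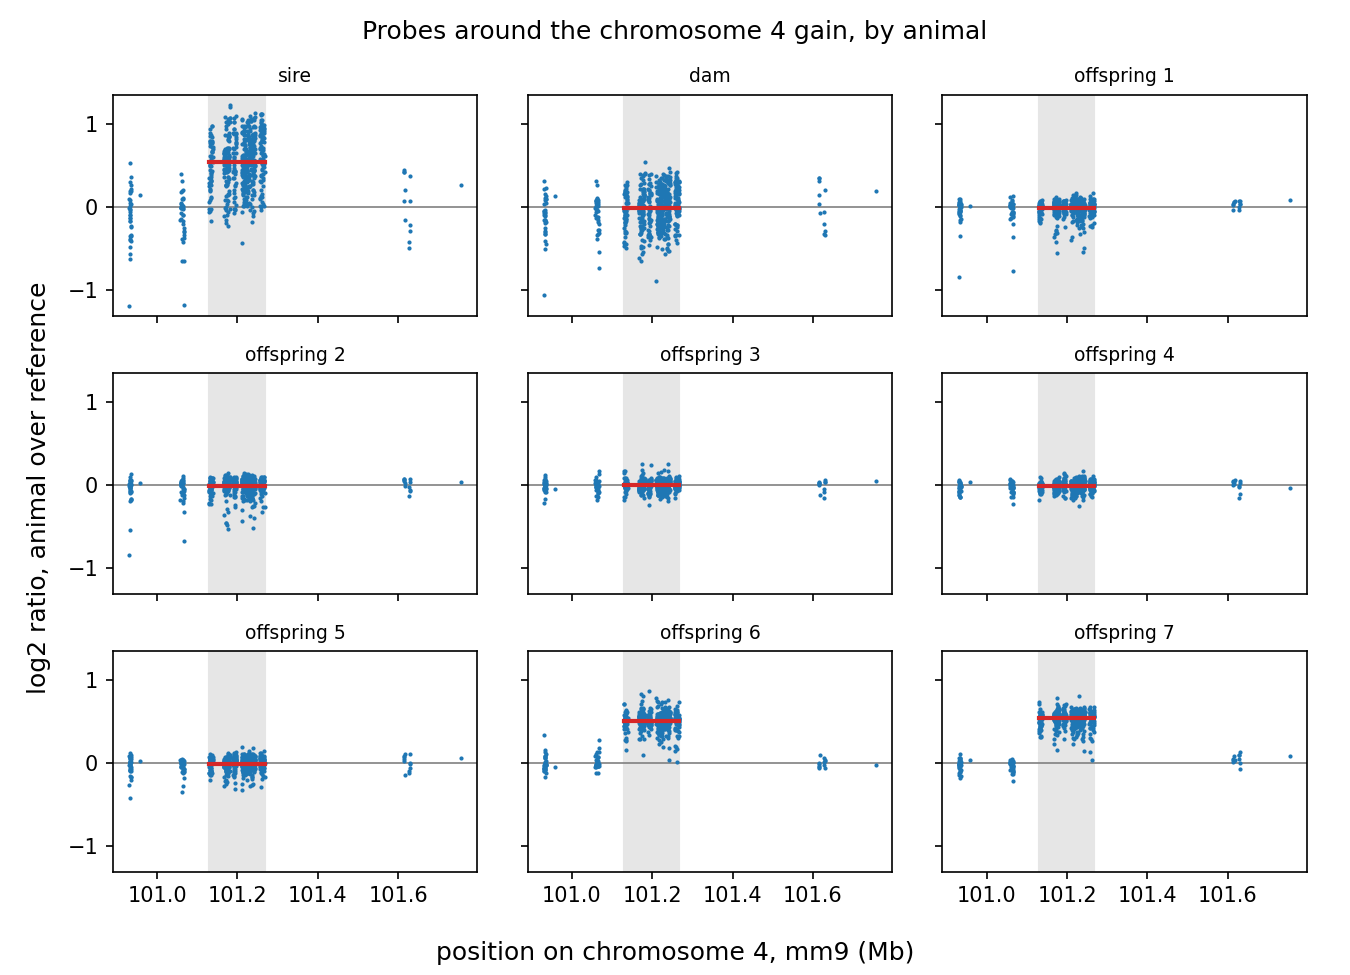
Each point is the log2 ratio (animal over reference, mean of both dye orientations) of 1 probe against its mm9 position on chromosome 4 in Mb, with 1 panel per animal. Grey marks the 138286 bp of the gain and the red line its mean, which is 0.54 in the sire, 0.51 in offspring 6 and 0.54 in offspring 7 and near 0 in the other animals.

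A loss on chromosome 3 was the largest segregating difference. In the called region from 25432440 to 25435605, with 5 probes, the mean log2 ratio was -1.32 in the dam and 0.14 in the sire. Offspring 3 to 7 carried the loss, with -1.39, -1.40, -1.44, -1.52 and -1.42 in that order, and offspring 1 and 2 did not. Over the whole tiled stretch of 9 probes from 25421508 to 25435605, the means were -1.60 in the dam, -1.58 in offspring 3, -1.57 in offspring 4, -1.66 in offspring 5, -1.67 in offspring 6 and -1.62 in offspring 7. They were 0.012 in the sire, 0.015 in offspring 1 and 0.0037 in offspring 2. Depth varied along the stretch, with an SD over the 9 probes of 1.05 in the dam. For the 5 carriers among 7 offspring no departure from even odds was detected (exact two-sided binomial p = 0.453, Benjamini-Hochberg adjusted p = 0.484). The test could not pass at 5 of 7. The carriers were also the animals with less Y signal, described next, so it decides nothing about how the loss is passed on.

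The animals with this loss were those with more X and less Y signal than the male reference. The 48 X probes had a mean log2 ratio of 0.91 in the dam and -0.048 in the sire, as the labels of the parents require. They read 0.95 in offspring 3, 0.95 in offspring 4, 0.91 in offspring 5, 0.92 in offspring 6 and 0.95 in offspring 7, against -0.013 in offspring 1 and -0.017 in offspring 2. The 3 Y probes averaged -4.06 in the dam and -0.056 in the sire, and -3.61, -3.74, -3.12, -3.21 and -3.82 in offspring 3 to 7. They averaged -0.0099 in offspring 1 and 0.013 in offspring 2. The SD over these 3 probes was 2.78 in the dam and 2.49 to 2.58 in offspring 3 to 7, against 0.11 in the sire. The Y probes thus differed widely in depth, and their mean is a rough value.

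A single region met the carrier rule in all 9 animals, as a loss. It lies on chromosome 14 from 52811677 to 53961747 (mm9) and holds 42 probes, mostly in a pair of tiled stretches between 53708609 and 53763828. Over the 37 probes of those stretches the mean log2 ratio was -0.45 with an SD of 0.023 between the 9 animals, and the animals ranged from -0.50 to -0.43. With 1 reference, it cannot be told whether the 9 animals or the reference differ. The lymphocyte receptor list, fixed because a loss of such genes in tail DNA can mark lymphocyte DNA, was not matched to positions. Whether it covers this loss or the other chromosome 14 region described next was therefore not tested.

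**Figure D2:**
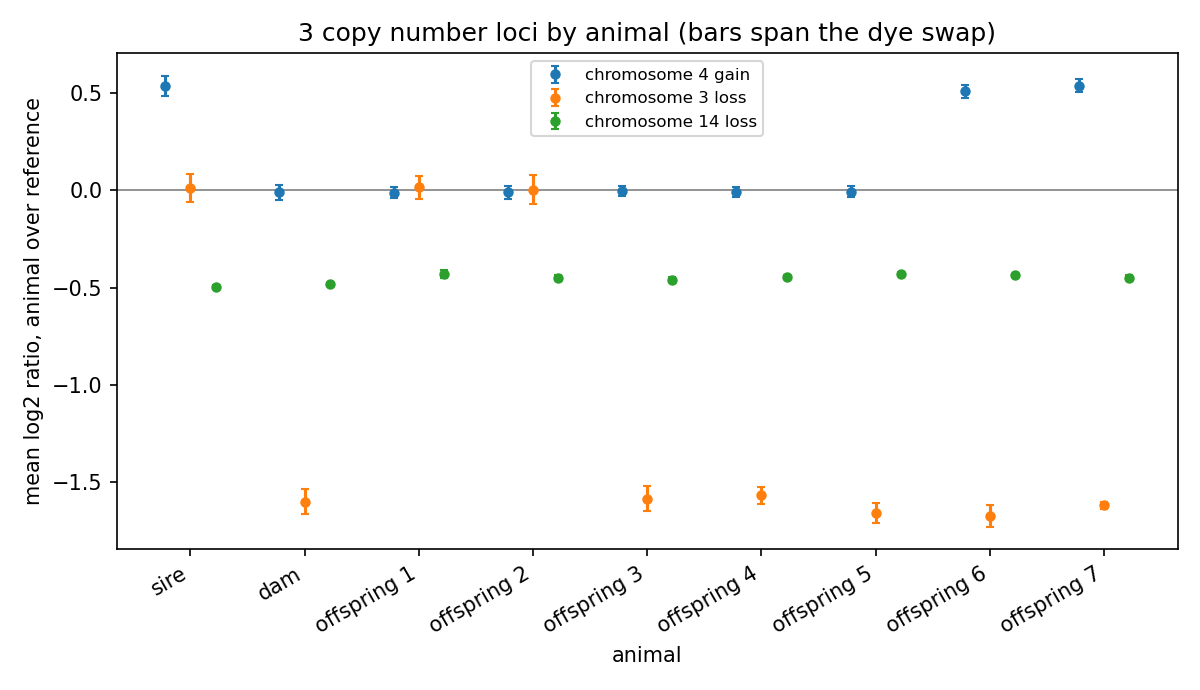
Points are the mean log2 ratio (animal over reference) of each animal over the chromosome 4 gain, the chromosome 3 loss and the chromosome 14 loss, and bars span the values of both dye orientations. The chromosome 4 gain is seen in the sire and offspring 6 and 7, the chromosome 3 loss in the dam and offspring 3 to 7, and the chromosome 14 loss in all 9 animals.

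Only 1 region met the rule for offspring-only changes, on chromosome 14 from 54176697 to 54219575 with 5 probes. It was a loss with 2 carriers among the 7 offspring, with means of -0.36 in offspring 6 (SD over probes 0.076) and -0.31 in offspring 2 (0.18). The other 5 offspring were undecided, but all 7 lay between -0.36 and -0.22, and offspring 1 read -0.32. The parents averaged -0.098 (sire, SD over probes 0.45) and -0.079 (dam, 0.34). With that spread over 5 probes, their status as non-carriers, on which the class rests, is uncertain. Their dye orientations were of opposite sign, at 0.044 and -0.24 in the sire and 0.10 and -0.26 in the dam. With normexp and loess the call ended, since offspring 6 read -0.24 (SD 0.13) and offspring 2 -0.23 (SD 0.21), short of the 0.3 required. After loess alone offspring 6 read -0.39 and offspring 2 -0.27, and no animal had a segment called as a loss there. With 5 probes and no mean beyond -0.36, the region could not pass where at least 10 probes or a mean of 0.5 were required.

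In all, 1260 autosomal segments were called, 776 of them in the sire and 270 in the dam. The offspring had 6, 44, 4, 5, 2, 71 and 82 segments in the order of their numbers. The rule called 19 segments on the dye component, 0 of them in the sire. That count misses any false call that follows the animal's DNA in both orientations. It therefore gives no false-call rate for the 1260 segments. The segments merged into 929 regions (477 gains and 452 losses), with a median of 8 probes and 833 bp. Of these, 869 were segregating, 58 met no class, and 764 of the segregating regions had no carrier among the offspring. For 1174 of the 1260 segments at least 1 of 10000 random windows was as large. After the chromosome 3 loss, the 9 largest segregating regions were all losses of 5 or 6 probes, on chromosomes 3, 4, 5, 6, 9 and 13, with sire means from -0.93 to -0.79 and dam means from -0.67 to -0.34. In them offspring 1 and 2 ranged from -0.62 to -0.20 and offspring 3 to 7 from -0.15 to 0.23. Both parents and offspring 1 and 2 were scanned on 1 day and offspring 3 to 7 on other days. Offspring 1 and 2 also shared a slide with no other animal. In these 9 regions the split between offspring therefore cannot be told apart from scan day or slide. X and Y signal split the offspring in the same way, although the dam, with less Y signal, also read low. With a loess fit of the ratio on intensity, added after the data were seen, the total was 193 regions, with 76 segments called in the sire and 93 in the dam. Of the 1046 segments first called in the parents, 98 overlapped a segment of the same animal and direction called after loess. Limited to segments of 20 or more probes, also added afterwards, 25 regions were called, among them the chromosome 4 gain and the chromosome 14 loss. In none of the remaining regions was an offspring a carrier, and the largest carrier there was mostly the sire.

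**Figure D3:**
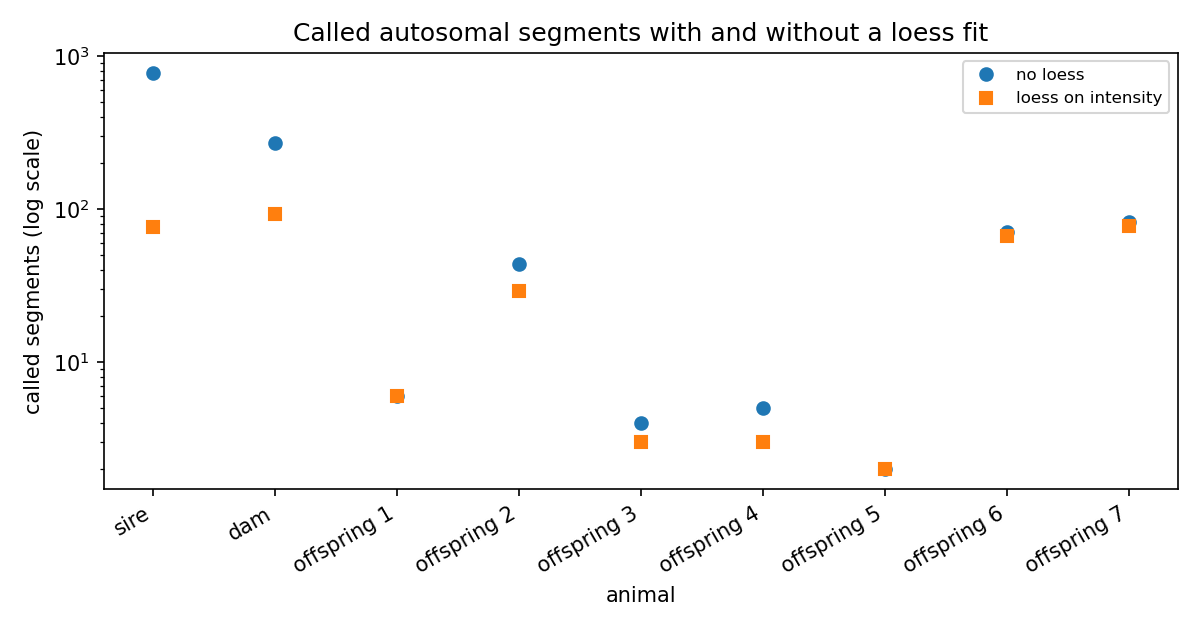
The number of called autosomal segments (log scale) is shown for each animal without and with a loess fit of the log ratio on intensity. The sire falls from 776 to 76 and the dam from 270 to 93, whereas offspring 6 goes from 71 to 67 and offspring 7 from 82 to 78.

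Segregation was tested for 483 regions with 1 carrier parent and at least 1 decided offspring. The other parent could be a non-carrier or undecided. In 397 the carriers departed from even odds at an adjusted p of 0.05 (exact two-sided binomial test, smallest p = 0.0156), and all 397 had no carrier among the offspring. No region departed through an excess of carriers. Even odds presume 1 heterozygous parent and another parent without the change. That does not describe regions where the other parent was undecided and read almost as far from 0. On chromosome 11 from 76356695, for instance, the sire read 0.33 and the undecided dam 0.28, with no carrier offspring. The 397 departures therefore decide nothing about how a change is passed on. After the loess fit the carrier parent was still called, in the same direction, at 7 of these 397 regions. The number of regions was 226 with carriers taken at 0.2 and 47 at 0.5.

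Between offspring and parents, 82878 of 135900 probes differed at an adjusted p of 0.05 by limma (7 offspring, 2 parents), 39286 higher and 43592 lower in the offspring, with a median absolute log2 difference of 0.22 among those called. By means of tiled stretches the balance turned, with 1427 stretches higher and 861 lower in the offspring. Without the sire, 50292 probes passed, but the parent arm is then the dam alone and the spread comes from the offspring only. After loess 61613 passed, 44495 of them among the 82878, and with normexp and loess 56448 passed, 40868 of them among the 82878. Of the 10 probes with the largest difference, 9 were higher in the offspring. The largest, on chromosome 12 from 3632831 to 3632881, differed by 1.81 with a standard error of 0.45 (limma adjusted p = 0.00595). At that probe the sire read -2.67, the dam -1.64, offspring 1 and 2 -1.28 and -1.30, and offspring 3 to 7 from -0.11 to 0.31. The one lower probe, on chromosome 4 from 30872946 to 30873005, differed by -1.38 with a standard error of 0.36 (limma adjusted p = 0.00833). The 8 others lay on chromosomes 5, 7, 8, 9, 10, 11, 15 and 19 and differed by 1.24 to 1.53. At those on chromosomes 5, 9, 15 and 19, offspring 1 and 2 read from -1.55 to -1.05. The dam read from -1.39 to -1.17 there and the sire from -2.31 to -1.90. At these probes the offspring were split, and the split cannot be told apart from scan day or slide. At those on chromosomes 7, 8, 10 and 11, offspring 1 and 2 read above both parents. Both parents lay on slide 1, which held no offspring, so slide and parenthood cannot be told apart. With slide as a random block 84355 probes passed, but the fitted slide correlation was -0.045, so this block did not adjust the contrast for slide. With scan day as a block 66735 passed, and within scan day 1, which held both parents and offspring 1 and 2, 64128.

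Sire and dam, with 1 animal each, are compared by their values. A limma fit of 3 groups with the offspring giving the spread, added after the data were seen, called 0 of 135900 probes (9468 at an unadjusted p under 0.05). That fit decides nothing, since it called none of the probes of the chromosome 4 gain either, where the offspring themselves differ and widen the spread. Autosome means differed by -0.012 to 0.029 (sire minus dam), and in 101 of the 929 regions the animals differed by at least 0.3. The log2 ratios of both orientations correlated across autosomal probes with r = 0.76 in the sire and 0.61 in the dam, against 0.11 and 0.19 in offspring 1 and 2 and -0.46, -0.46, -0.27, -0.17 and -0.36 in offspring 3 to 7. These are correlations across probes within an animal, and probes are not independent replicates. The noise between neighbouring probes of the dye-averaged ratio was 0.16 in the sire and 0.14 in the dam, and 0.048 to 0.059 in the offspring.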

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

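The loess fit without background correction, the minimum of 20 probes, the calling of regions from the means of tiled stretches, the calling from offspring alone, the scan day fits and the fit of sire, dam and offspring as 3 groups were chosen after seeing the data, and the rest were fixed before the data were examined. The chromosome 4 gain kept its direction in all its carriers under every signal, centring, filter and orientation alternative (means from 0.47 to 0.59), as did the chromosome 3 loss (-1.96 to -1.52) and the chromosome 14 loss from 53708609 (-0.59 to -0.41). Over all carriers at the 7 loci called from stretch means, 158 values moved by less than the spread of the dye swap, 33 by more, and 1 reversed: the sire at chromosome 14 from 54287702 read 0.035 after loess without background correction. Values of 1 dye orientation alone fall among the 158 by construction, since each lies within that spread of the mean of both. A carrier also has the same sign in each orientation by rule. The orientation alternatives therefore add no evidence of stability at these loci. Counts were far less stable. The total of 929 regions became 187 with normexp and loess, 146 at a threshold of 0.5, 1446 with at least 3 probes, 307 with at least 10, 1605 at penalty 15, 365 at penalty 40, 574 on the Cy3 arrays alone, 193 with loess alone, 25 with at least 20 probes, 128 from offspring segments only and 7 from stretch means. The 869 segregating regions became 163, 145, 1319, 298, 1546, 300, 488, 150, 24, 67 and 6 under the same settings. The count of offspring-only regions, 1 at first, became 0 with normexp and loess, at a threshold of 0.5, with at least 10 or 20 probes and from stretch means. It became 4 at a threshold of 0.2, 6 with at least 3 probes, 2 at penalty 40, 3 on the Cy5 arrays alone and 12 on the Cy3 arrays alone. The 1 region left with loess alone is not the one first called. The region shared by all 9 animals was lost at a threshold of 0.5, which left 0. The cause of these changes was not tested apart from loess. Other alternatives stayed within 1.5 times the main count. Offspring versus parents gave 50292 to 83828 probes when 1 animal was left out, and the lowest count was without the sire, where the dam is the only parent (72841 without the dam). With 1 parent left, the spread comes from the offspring only. With 2288 of 3851 stretches called (1427 higher and 861 lower in the offspring), the count by stretch is not on the same scale. Regions departing from even odds numbered 226 with carriers at 0.2 and 47 with carriers at 0.5, against 397. Over probes of called regions alone the dye swap correlation was 0.89 in the sire, 0.79 in the dam, and 0.33, 0.49, -0.23, -0.25, 0.039, 0.43 and 0.39 in the offspring in order of number, so the sign turned in offspring 5, 6 and 7. Calling required both orientations to agree, so these probes were selected partly for agreement. The rise therefore decides nothing about the quality of the arrays. The correction for base composition and the gene lists were not run. No paired analysis was possible because each animal is a group member of its own, with no matched pairs.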

Other observations

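All tests in this part were chosen only after the results were seen. Apart from the loci of the report, a short region on chromosome 8 from 97526377 to 97527443 (7 probes, chosen after its values were seen) differed between animals. Its mean log2 ratio was 0.71 in the sire, 0.40 in the dam, -0.057 in offspring 1, 0.46 in offspring 2, 0.72 in offspring 3, 0.11 in offspring 4, -0.12 in offspring 5, 0.43 in offspring 6 and 0.36 in offspring 7. It is also among the 73 regions of short gains described next, whose profile it did not follow (r = -0.070). The sire, offspring 2 and offspring 3 read far above the medians of those regions (-0.11, -0.28 and -0.080). The other animals read close to theirs, so part of the spread between animals may belong to that shared profile. None of the 35 values tested among the 7 offspring stood apart from the others by Dixon's criterion.

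Offspring 6 and 7 shared a set of short gains. Outside the chromosome 4 gain, the gains called in these 2 offspring merged into 73 regions of 5 to 14 probes on 19 autosomes, and 66 of the 79 gains of offspring 7, those on chromosome 4 included, overlapped gains of offspring 6. The regions' median was 0.37 in offspring 7, 0.33 in offspring 6, 0.29 in the dam, 0.081 in offspring 4, -0.042 in offspring 1, -0.080 in offspring 3, -0.11 in the sire, -0.14 in offspring 5 and -0.28 in offspring 2. Over the 7 animals not used to pick the regions, a region's profile correlated with the median profile of the others with a median r of 0.97, against -0.023 for 1000 random windows, so separate copy number differences on 19 autosomes are argued against. A trend with intensity is argued against too, since 94.8% of the segments of offspring 6 and 7 overlapped a segment of the same animal and direction called after loess. In the same correlations 69 of the 73 regions lay above 0.8 with the others. A candidate explanation is 1 sequence of varying amount that binds probes at many positions. These correlations do not single it out, since any factor common to the probes of these regions would also give a shared profile. The planned correction for base composition was not run and no probe sequence was used here, so the common factor stays open.

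The many short segments of the parents gave other values in the same tests. Of 1046 segments called in the parents, 9.37% overlapped a segment of the same animal and direction called after a loess fit on intensity, consistent with a trend of the ratio with signal strength. Inherited differences are argued against for most of them: over the 384 regions under 20 probes that both parents carry, a mean of 0.23 of the 7 offspring carried, and 332 had no offspring carrier. Sire and dam probe values outside called regions correlated with r = 0.93, above every pair from different slides. The other pairs on 1 slide gave 0.85 for offspring 1 and 2, 0.32 for offspring 3 and 4 and -0.33 for offspring 5 and 6, the last of these below most pairs from different slides, so sharing a slide did not as a rule bring a shared pattern. For the parents themselves, who alone lie on slide 1, slide and DNA preparation cannot be told apart from parenthood. For the 82878 probes of the offspring and parents comparison, only 4 splits set apart a pair of animals sharing a slide. Of these, 1 (the real split) called as many and the highest other called 0, and 4 splits are too few for a share under 0.05.

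The chromosome 3 loss may come from Y-linked copies in the male reference rather than from chromosome 3. In 9 of 9 animals the loss and the loss of Y signal were both present or both absent. An autosomal deletion passed on by the dam would leave each offspring the sire's copy, and so a ratio no lower than -1, whereas the highest mean among the 5 carrier offspring was -1.57 over the tiled stretch with a standard error over 9 probes of 0.34, and -1.39 in the called region with a standard error over 5 probes of 0.18. The depth varied by probe, and Y sequence was not compared, so the source of the signal stays a hypothesis.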
